A study of Bacillus subtilis PY79 with 10 samples.

How the data were processed

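Hi-C contact maps and chromatin immunoprecipitation sequencing (ChIP-seq) coverage of Bacillus subtilis PY79, a laboratory strain of a rod-shaped soil bacterium, were used. The series holds 10 libraries here: 6 Hi-C maps and 4 coverage tables, with 1 library in each group. Per the labels' protocols, cells grew in a defined rich medium at 37 °C and were fixed with 3% formaldehyde for 30 min, Hi-C used the restriction enzyme HindIII, and ChIP-seq used antibodies against named proteins.

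The Hi-C values are deposited by the authors as balanced maps, in which each entry is a fraction, the share of a row's contact that falls in a column. Each map has 404 rows and columns, its row totals lie between 0.998 and 1.00, and its values are rounded to 4 decimals. The diagonal and the nearest neighbours of each bin are 0, so contacts closer than 20 kb were not measured. The balancing method is not given in the sources used here. The chromosome length of 4033459 bp, taken from the coverage tables, over the number of bins gave a bin of 10 kb. The coverage values are deposited by the authors as per-base signal, the whole-number coverage at each of the 4033459 positions, with no scaling between libraries. The submitters' processing notes name Bowtie2 2.1.0 as a tool. The genome build is not given in the sources used here. The only annotation at hand was of another PY79 assembly (ASM2352161v1) whose length and start differ from those of the files, so none of its coordinates were used, and it served only for the number and order of ribosomal RNA genes. Regions are therefore given in the files' own coordinates, counted from 1, and splits by gene, by reading direction and by parS motif, as well as the gene lists chosen beforehand, were not analysed here.

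The read depth of the Hi-C maps is unknown, because balanced shares keep no counts. As a stand-in for noise, the scatter of a pixel around its neighbours on the same diagonal was taken at separations of 1000 to 2000 kb. It was 13.1% and 18.8% in the 10 and 30 min rifampicin maps, and 22.6%, 20.2%, 25.5% and 60.3% in the 0, 30, 60 and 90 min xylose maps, so that the 90 min map carries the largest error. Mean coverage per position was 75.2 in the SMC ChIP, 17.7 in the wild-type input, and 32.0 and 51.8 in the libraries titled input after 10 and 30 min of rifampicin. Medians were 32, 15, 14 and 25. Coverage was 0 at 2.04%, 0.0242%, 0.146% and 0.00786% of positions.

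Groups were taken from the titles. For the libraries titled input the labels contradict themselves: the titles say input, while other fields name an antibody (anti-GFP for the rifampicin libraries, anti-SMC for the wild type). They are called "titled input" where this matters.

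Each map was divided by the median of all pixels at the same circular separation and smoothed over 3 x 3 bins. The hairpin, the line of contacts that leaves parS at an angle to the main diagonal, was followed as the highest value at each separation among pixels whose midpoint lay within 300 kb of the labelled parS position, the window widening with separation. Strength was the median of these maxima over separations of 200 to 800 kb. Tilt was the distance covered on the terminus side over that on the origin side, from a line through parS over 200 to 1200 kb. Extent was the largest separation reached while enrichment was at least 2 in at least 8 of 10 consecutive separations, starting from 100 kb. After the data had been seen, straight lines through parS with 0.40 to 0.85 of the separation on the terminus side were also searched for the highest mean enrichment over 200 to 1200 kb, because maxima grow with noise and a mean along a line does not. Contact shares by separation, the log-log slope of mean contact over 50 to 500 kb, and an insulation score (log2 of the mean contact across a bin in a 100 kb square over the chromosome mean) were computed from the maps. Boundaries were local minima at least 0.2 below the mean of the maxima within 200 kb on each side, and were matched between maps within 2 bins. Intervals are 95% bootstrap intervals from 1000 draws (300 for slopes) of blocks within a map. They cover scatter within a map and no spread between cultures.

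Coverage was averaged in 1 kb bins and divided by each library's genome-wide median. The SMC ratio is the log2 of SMC ChIP over wild-type input, in the 4030 of 4033 bins whose input was at least 0.333 of the median. Local coverage is the log2 of a bin over the median of the surrounding 50 kb, with 0.1 added to both. Copies of a repeated profile were found, after the data had been seen, by sliding 2500 bp of the 30 min rifampicin library's strongest run along the chromosome in both orientations, with a Pearson r of at least 0.9 and a level within 0.8 to 1.25 times that of the template. The rule for named regions, set before the data were examined for genes, was applied to regions: the runs made of the highest 1% of bins of the SMC ratio (at most 20 runs), the 5 lowest runs, and the 10 deepest boundaries of the 0 min xylose and 10 min rifampicin maps. Bins whose starts lay at most 2 kb apart were joined into a run.

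With 1 library per group there is no test between groups, and values are compared with their intervals only. Alternatives fixed before the data were examined covered the expected value, smoothing, thresholds, separations, insulation squares, boundary depth and matching, scaling, bin size, input filter and window sizes. The hairpin functions were tested on simulated maps with a tilt of 1.78, 20 draws for each setting and 404 bins. With a peak of 2.7 and noise of 20%, made like the 0 min map, the maxima gave a strength of 2.72 ± 0.058 (SD over draws) and the straight line a mean of 2.64 ± 0.038. With a peak of 1.7 and noise of 60%, made like the 90 min map, the maxima gave 1.93 ± 0.058 and the straight line 1.70 ± 0.037, while the tilt was recovered as 1.77 ± 0.058 and 1.81 ± 0.059. In simulated coverage over 4033 bins, all 40 bins planted at a log2 ratio of 1.5 were among the 40 highest. The log2 scatter elsewhere was 0.095 in that simulation, against an SD over bins of 1.31 in the real SMC ratio. Recovery thus followed from the setting, and it checks the computation only, not the real high bins. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.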

Results

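The data describe how the chromosome of Bacillus subtilis is folded when RNA polymerase is stopped or removed. Condensin, a ring-shaped complex of SMC and partner proteins, is loaded at parS sites by the protein ParB and brings the chromosome arms flanking such a site together. In a Hi-C map this appears as a hairpin, a line of contacts that starts at parS and runs away from the main diagonal. The series title names the question: whether RNA polymerases act as moving barriers to condensin. In both Hi-C strains the native parS sites are deleted and 1 site is left at a new position. In the first strain it lies at -94 degrees (2980 kb) and cells received 25 µg/ml rifampicin, which blocks the start of transcription, for 10 or 30 min. In the second strain it lies at -59 degrees (3372 kb), and RpoC, the beta prime subunit of RNA polymerase, carries an ssrA tag. There, 0.5% xylose switches on SspB, an adaptor that hands tagged proteins to a protease, and maps were made at 0, 30, 60 and 90 min. The 4 coverage tables are an SMC ChIP and an input of the wild type, and libraries titled input of a strain with RpoC-GFP and a parS site at +26 degrees after 10 and 30 min of rifampicin. Each group has 1 library, so no value below has a replicate check, and the brackets give 95% bootstrap intervals within a map.

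Before any xylose, the strain with tagged RNA polymerase showed a strong, tilted hairpin. Along the straight line through parS that held most contact, pairs of loci 200 to 1200 kb apart met 3.01 (2.85 to 3.23) times as often as the median pair at the same separation. The same search at 29 places elsewhere on the chromosome gave a median of 1.08 and at most 1.42. The hairpin was not symmetric: 64% of the separation lay on the terminus side of parS, a ratio of 1.78 (1.63 to 1.94) of the distance covered toward the terminus to that toward the origin. The line started at the labelled parS bin, since moving its start by up to 300 kb in steps of 10 kb, with separations of 200 to 600 kb, gave no higher mean than the labelled position in the 0 and 60 min maps, and best starts within 20 kb of it in the 30 and 90 min maps.

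The hairpin weakened with time in xylose. Mean enrichment on the best line was 2.63 (2.5 to 2.8) at 30 min, 1.98 (1.89 to 2.08) at 60 min and 1.84 (1.77 to 1.93) at 90 min. Differences from 0 min were -0.38 (-0.44 to -0.33), -1.03 (-1.17 to -0.93) and -1.17 (-1.4 to -0.98), each larger than the scatter within the maps. At 90 min the line still lay above the 29 background places, which reached at most 1.43. The measure chosen before the data were examined, the median of the maxima over 200 to 800 kb, was 3.18 (2.7 to 3.64), 2.87 (2.37 to 3.15), 2.01 (1.74 to 2.21) and 2.02 (1.94 to 2.14) at 0, 30, 60 and 90 min. Its background in 15 other places rose from a median of 1.37 at 0 min to 1.60 at 90 min, and in simulated maps with the noise of the 90 min map this measure came out at 1.93 where the planted peak was 1.7.

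The hairpin's length did not pass its preset rule in any map. Enrichment next to parS lay below 2 at 100 kb, where the rule starts, and the extent came out as 0 kb in all 6 maps. A measure added afterwards, the separation at which the excess along the line fell below 50% of its highest value, gave 2200 kb at 0 and 30 min. At 60 and 90 min this level was not reached up to 2400 kb. Along the line of the 0 min map, with 64% on the terminus side, enrichment at separations of 1600 to 1800 kb was 3.55 at 0 min, 3.00 at 30 min, 2.29 at 60 min and 2.09 at 90 min, with SDs over separations of 0.12, 0.11, 0.13 and 0.29. Along each map's own line, with 62% at 60 min and 58% at 90 min, the last 2 values were 2.12 and 1.69. Nearest to parS, at 200 to 400 kb of the 0 min line, enrichment was 2.24, 2.01, 1.57 and 1.62.

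**Figure D1:**
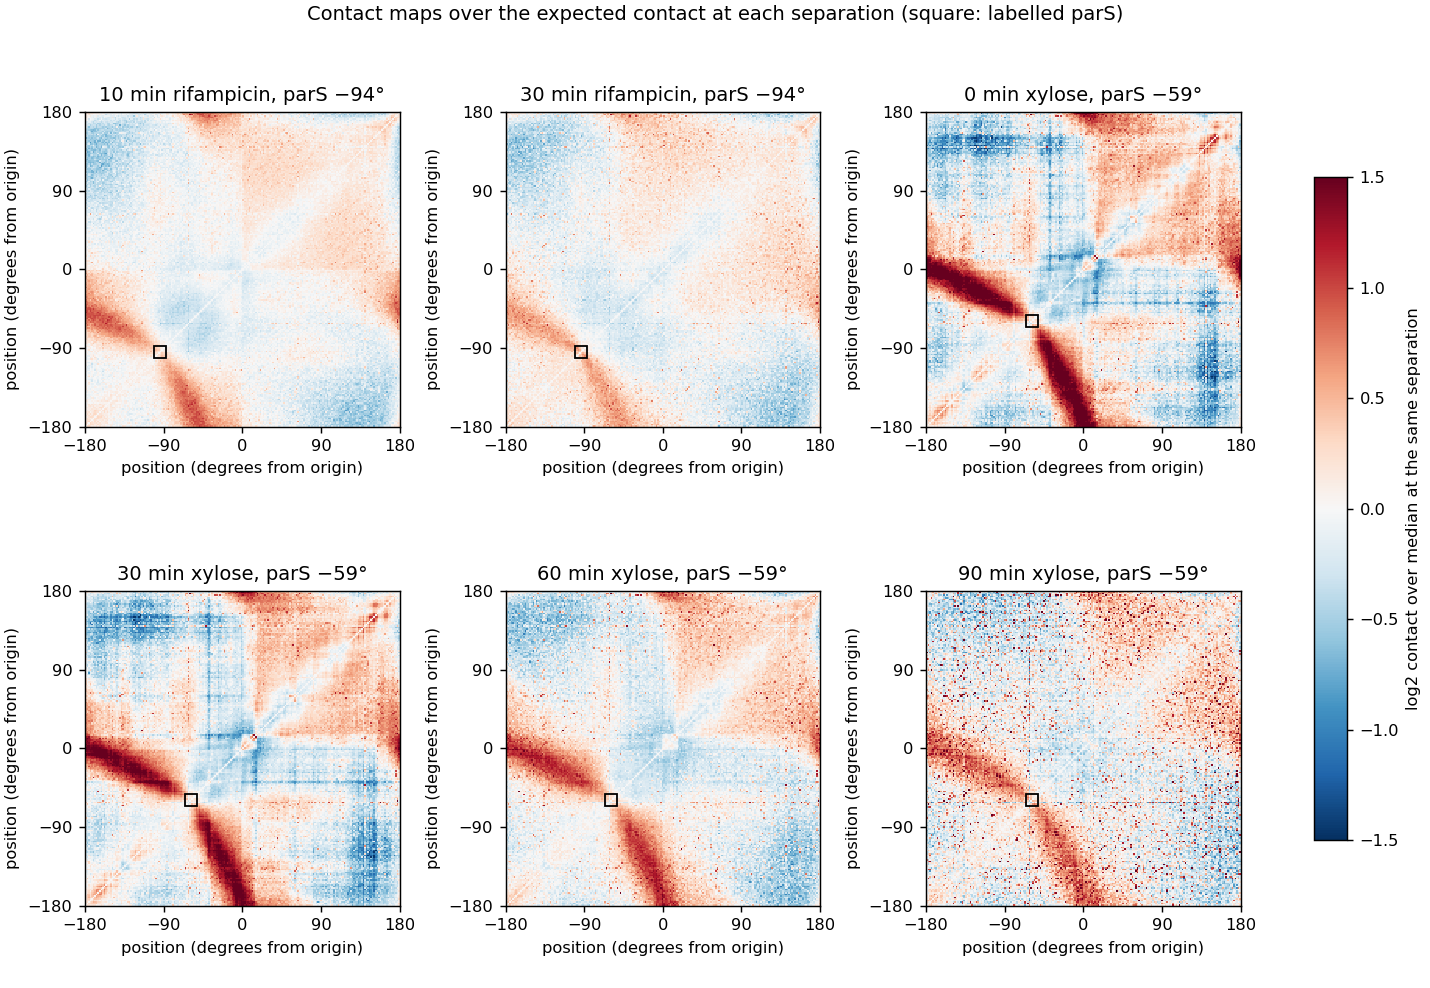
Contact over the median contact at the same separation, on a log2 colour scale, for the 6 Hi-C maps, with both axes in degrees from the origin and a square at the labelled parS site. A red line leaves parS in every map and covers more distance on the terminus side; its mean enrichment is 3.01 at 0 min of xylose, 1.84 at 90 min, and 1.7 and 1.53 in the rifampicin maps.

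**Figure D2:**
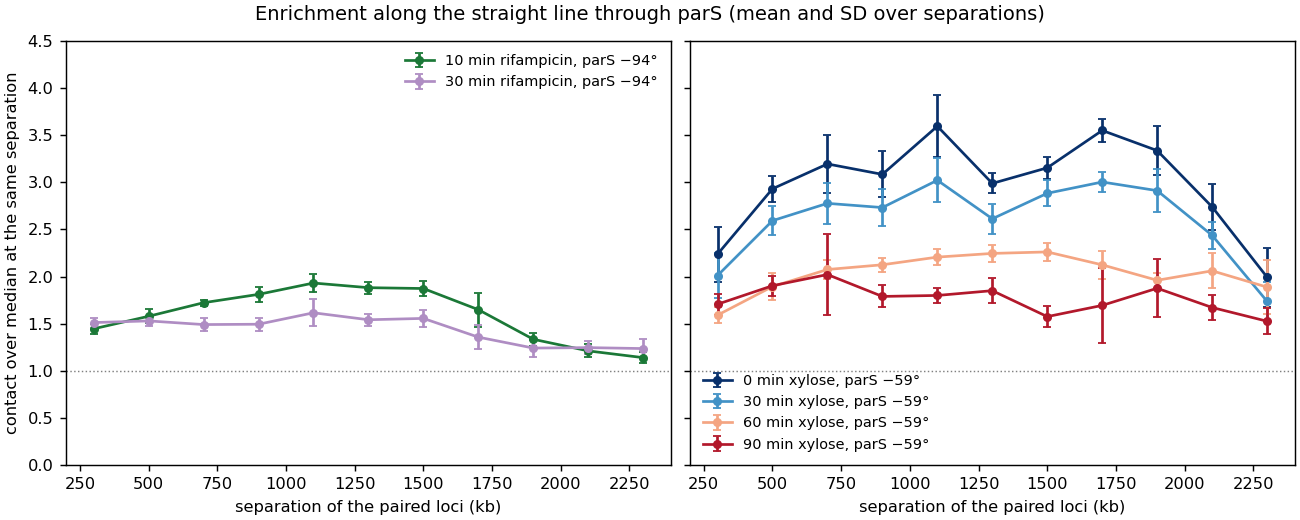
Mean contact over the median at the same circular separation along each map's own straight line through parS, in windows of 200 kb with the SD over separations as bars. The horizontal axis is the separation of the paired loci in kb, counted on the path through parS. The dotted line marks the median contact. At 0 min of xylose the points lie between 1.99 and 3.60, and at 90 min between 1.52 and 2.02.

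Tilt at 30 min did not differ from that at 0 min beyond its interval, and at 60 min it was lower by the maxima. From the maxima it was 1.82 (1.73 to 1.92) at 0 min, 1.82 (1.74 to 1.92) at 30 min and 1.65 (1.56 to 1.74) at 60 min. The differences from 0 min were 0.0069 (-0.019 to 0.040) and -0.17 (-0.31 to -0.05), the last of which excludes 0. The straight-line search gave 1.78, 1.78 and 1.63, and its difference of -0.15 (-0.45 to 0.07) at 60 min includes 0. At 90 min the 2 ways of measuring went in opposite directions. The maxima gave 2.34 (1.78 to 2.75) and the straight line 1.38 (1.33 to 1.56), with differences from 0 min of 0.52 (-0.05 to 0.96), which includes 0, and -0.40 (-0.62 to -0.07), which excludes it. No direction is given for that map because the measures disagree.

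Rifampicin maps were compared between 10 and 30 min, without an untreated map of that strain, which was not analysed here. Both showed a weak hairpin tilted the same way. Mean enrichment on the best line was 1.7 (1.63 to 1.78) at 10 min and 1.53 (1.5 to 1.56) at 30 min, a difference of -0.17 (-0.24 to -0.11), with backgrounds that reached at most 1.19 and 1.16. The median of the maxima differed by less, 1.61 (1.54 to 1.72) against 1.57 (1.54 to 1.59), a difference of -0.03 (-0.16 to 0.03) that includes 0. Along the line of the 10 min map, with 62% on the terminus side, enrichment at 1000 to 1200 kb was 1.93 at 10 min and 1.56 at 30 min, while at 200 to 400 kb it was 1.44 and 1.53. Tilt from the maxima was 1.67 (1.60 to 1.73) and 1.69 (1.59 to 1.77), a difference of 0.01 (-0.04 to 0.08). By straight line it was 1.63 and 1.86, a difference of 0.23 (-0.28 to 0.24) that also includes 0. In both maps the excess fell below 50% of its highest value at 1800 kb, and the best start of the line lay 30 kb from the labelled parS position. The 2 strains differ in parS position and genotype, so their values stand side by side without a comparison.

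The share of short-range contact fell in the xylose series. Contact at separations of up to 50 kb made up 8.49% of all contact at 0 min, 7.63% at 30 min, 6.08% at 60 min and 5.80% at 90 min. The differences from 0 min were -0.86 (-1.08 to -0.69), -2.41 (-3.00 to -1.99) and -2.7 (-3.39 to -2.17) percentage points. Contact at 50 to 200 kb went from 19.2% to 18.1%, 15.5% and 12.6%, and contact beyond 1000 kb from 32.8% to 33.7%, 36.9% and 39.7%. Because rows are balanced to 1, a loss at one range appears as a gain at another. A larger share of random ligations in later maps would also lower the short-range share and flatten the slope, and was not separated from it here. The slope of contact on separation over 50 to 500 kb flattened from -0.63 at 0 min to -0.57, -0.43 and -0.30. Over 30 to 200 kb it was -0.44, -0.40, -0.30 and -0.34, steeper at 90 min than at 60 min. Under rifampicin the slope over 50 to 500 kb was -0.33 at 10 min and -0.32 at 30 min. Contact within 50 kb was 5.28% and 5.66% there, a difference of 0.37 (0.28 to 0.47) percentage points, while contact at 50 to 200 kb was 13.9% and 12.9%. Over 30 to 200 kb the order of the rifampicin slopes turned, to -0.25 at 10 min and -0.35 at 30 min.

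**Figure D3:**
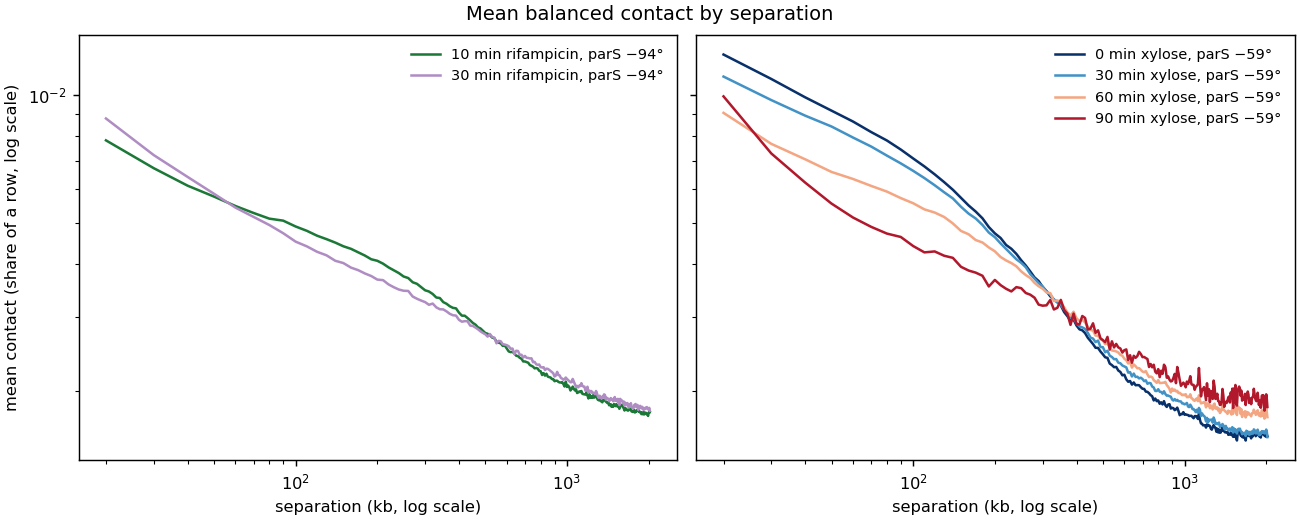
Mean balanced contact, as a share of a row, against separation in kb, both on log scales, for the rifampicin maps and the xylose maps. Over 50 to 500 kb the xylose curves flatten with time, with slopes of -0.63 at 0 min and -0.30 at 90 min. Over 30 to 200 kb the 90 min curve, at -0.34, is steeper than that at 60 min, at -0.30.

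Insulation showed the same flattening along the chromosome. Random ligations could also lower its spread, and they are weighed below. The SD of the insulation score over bins was 0.249 (0.197 to 0.291) at 0 min, 0.240 at 30 min, 0.190 at 60 min and 0.141 (0.112 to 0.166) at 90 min. The difference from 0 min was -0.0087 (-0.021 to 0.0043) at 30 min, which includes 0, -0.058 (-0.081 to -0.035) at 60 min and -0.11 (-0.15 to -0.066) at 90 min. The 0 min map had 14 boundaries. The deepest lay at 2000001 to 2010000, with a depth of 0.58 on the log2 scale, followed by 160001 to 170000 (0.51), 2520001 to 2530000 (0.46), 3600001 to 3610000 (0.42) and 1210001 to 1220000 (0.32). The other members of the 10 deepest lay at 3940001, 3910001, 1840001, 3250001 and 3170001, each 10 kb long, with depths from 0.23 to 0.27. The median depth of these 10 was 0.30 at 0 min, 0.28 at 30 min, 0.22 at 60 min and 0.17 at 90 min. The boundary at 2000001 went from 0.58 to 0.56, 0.39 and 0.17, and that at 160001 from 0.51 to 0.56, 0.27 and 0.22. These 10 were picked for their depth at 0 min, which by itself lowers later values.

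Of the 14 boundaries at 0 min, 8 had a boundary within 2 bins at 30 min, 6 at 60 min and 4 at 90 min. Shifting the later boundaries around the circle matched 1.39, 0.97 and 2.18 on average. As many or more were matched in 5, 4 and 58 of 404 shifts, so the 90 min count was not separated from chance. The 404 shifts of boundaries include the observed placement itself, which these means and counts therefore contain. That map has 13 boundaries and the highest noise. The SD in the rifampicin maps was 0.141 (0.107 to 0.167) at 10 min and 0.159 (0.133 to 0.184) at 30 min. They had 3 and 2 boundaries, of which 1 was shared, as in 30 of 404 shifts. The 3 at 10 min lay at 1910001 to 1920000, 1970001 to 1980000 and 1 to 10000, with depths of 0.23, 0.22 and 0.20. The SD difference of 0.018 (0.0024 to 0.035) between the rifampicin maps turned to -0.0047 with a 200 kb square.

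**Figure D4:**
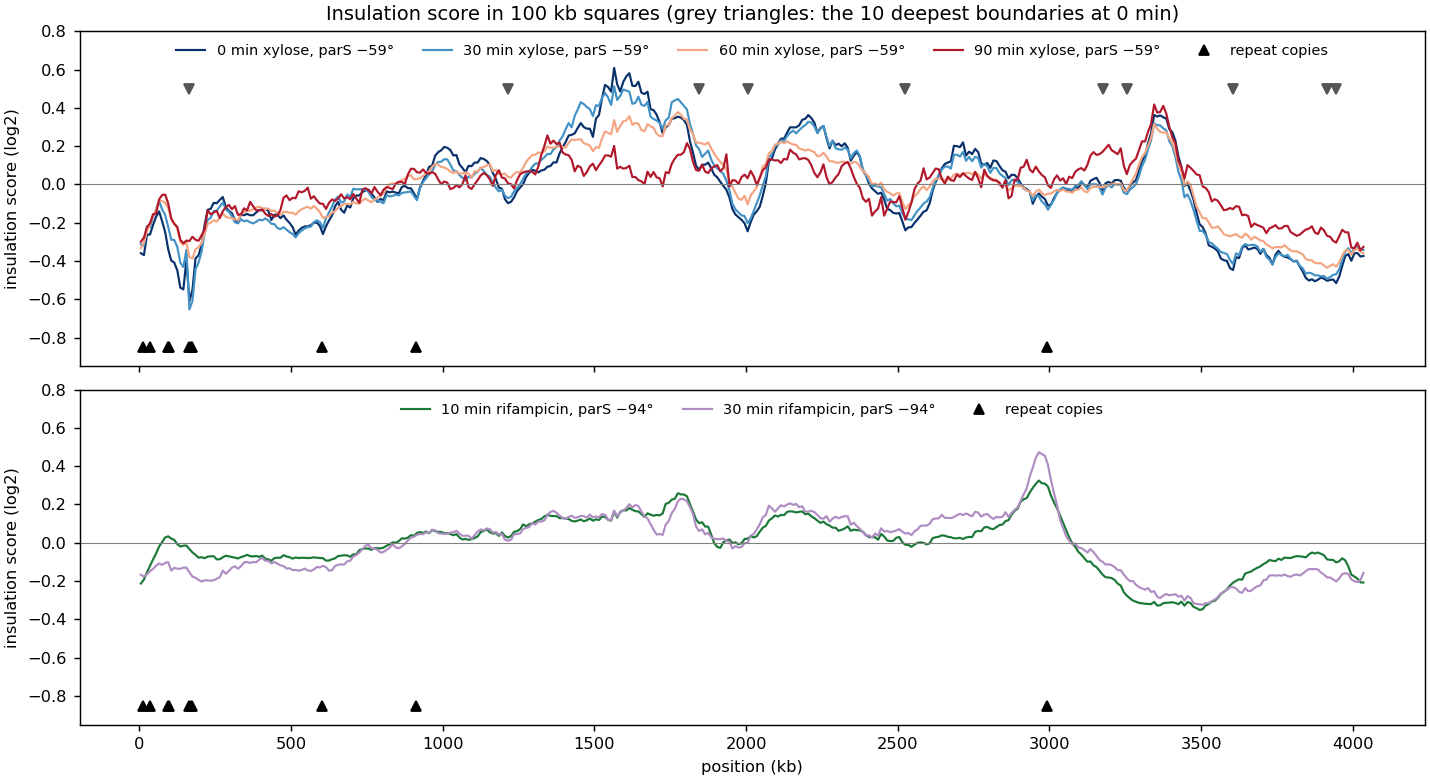
Insulation score (log2, 100 kb squares) against position in kb for the xylose maps (top) and the rifampicin maps (bottom), with grey triangles at the 10 deepest boundaries of the 0 min map and black triangles at the copies of a repeated coverage profile. The trough at 2000001 to 2010000 becomes shallower with time in xylose, from a depth of 0.58 to 0.17.

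SMC in wild-type cells was more abundant around the origin than around the terminus. The SMC ratio (log2 SMC ChIP over input) had a median of 1.51 in the 200 kb around the origin and of -1.29 in the 200 kb around 170 degrees. The difference of 2.80 (2.18 to 3.35) corresponds to a 6.97 times higher ratio. If the wild-type input is what its title says, dividing by it takes out the higher gene copy number near the origin, but its description names an anti-SMC antibody. From origin to terminus the ratio fell by 1.27 per Mb on the right arm (slope -1.27, -1.57 to -0.93) and by 1.31 per Mb on the left arm (slope -1.31, -1.57 to -1.06). The 100 kb windows with the highest medians were 3900 to 4000 kb at 1.68 and 3800 to 3900 kb at 1.60. The decline was not smooth: the window at 500 to 600 kb had a median of -0.09 between neighbours at 0.97 and 0.71, and that at 2500 to 2600 kb, on the left arm, had -1.65, the lowest of all 40 windows.

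The highest 1% of bins, 40 bins at a ratio of 3.65 or more, formed 11 runs. The highest was the single bin at 512001 to 513000, with a ratio of 4.84, where SMC coverage was 36.1 times its median and input 1.26 times. It was followed by 910001 to 916000 (4.57), 91001 to 99000 (4.27), 598001 to 601000 (4.15), 30001 to 33000 (4.13) and 4030001 to 4031000 (4.11). The others were 165001 to 176000 (4.04), 161001 to 163000 (4.03), 2994001 to 2996000 (3.96), 2990001 to 2992000 (3.96) and 10001 to 15000 (3.88). The 5 lowest runs were 1858001 to 1861000 (-5.35), 2008001 to 2026000 (-4.90), 1843001 to 1850000 (-4.69), 1981001 to 1984000 (-4.67) and 1864001 to 1865000 (-4.52), all near the terminus.

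Most of the high runs fell in copies of 1 repeated profile. The profile occurred 10 times, 9 times in forward and 1 time in reversed orientation, with a Pearson r over positions of at least 0.907 against at most 0.860 elsewhere. The copies held 36 of the 40 highest bins. They formed 7 clusters which, from the origin on, held 1, 1, 2, 3, 1, 1 and 1 copies, the last of them reversed. The other PY79 assembly carries 30 ribosomal RNA genes in 10 operons, which form 7 clusters with the same sizes and orientations in the same order, so the copies are taken here as the ribosomal RNA operons, the most heavily transcribed genes of growing cells. Clusters of these sizes and orientations can be arranged in 210 orders. The median SMC ratio over copies was 3.72, against 1.22 in the median of 10000 random lists of 10 blocks matched on input coverage, none of which reached it (highest 1.92). Reads from near-identical copies may be shared among them by the aligner, so the value of a single copy is uncertain. In sequence 1 to 3 kb outside the copies, SMC coverage was 0.62 times the local median (0.18 to 1.11 over 9 copies). The wild-type input was at 0.90 there, and the libraries titled input at 0.76 after 10 min and 0.82 after 30 min of rifampicin. The 1 kb bins directly beside the copies were left out, and some of them were high in SMC, as given below.

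Coverage of the libraries titled input fell from origin to terminus in each of them. The ratio of the 200 kb around the origin to the 200 kb around 170 degrees was 3.00 (2.59 to 3.43) in the wild type, 2.86 (2.38 to 3.86) after 10 min of rifampicin and 2.83 (2.26 to 3.27) after 30 min. The 30 min value differed from the 10 min value by -0.024 (-0.82 to 0.021), which includes 0. By mean coverage the ratios were 2.85, 3.85 and 3.49, which puts the wild type lowest instead of highest, so no order between the libraries is given. The wild type is another strain without rifampicin. Medians of whole-number coverage are coarse at this depth, since the genome-wide median of the 10 min library is 14.

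At the repeat copies, which were located in the 30 min rifampicin library, both rifampicin libraries stood above the wild-type input. Their coverage there was 5.92 times the local 50 kb median after 10 min (2.74 to 7.64 over 10 copies) and 5.10 times after 30 min (2.48 to 6.54). The wild-type input was at 1.4 times (1.2 to 1.7), and the SMC ChIP at 9.31 times (3.91 to 21). Coverage at the copies was lower at 30 min than at 10 min, by a ratio of 0.861 (0.844 to 0.952, with the copies taken as independent although they may share reads). Outside the copies, 317 bins of similar level had a median ratio of 0.926, with quartiles of 0.875 and 0.982, so most of these bins fell too. The spread of local coverage over the whole chromosome was also wider in the rifampicin libraries, with an SD of 0.97 and 0.91 on the log2 scale against 0.34 in the wild-type input. Outside the copies, local coverage of the rifampicin libraries correlated across 1 kb bins with each other (r = 0.979) and with the wild-type input (r = 0.838 and 0.808). Bins are not independent replicates.

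**Figure D5:**
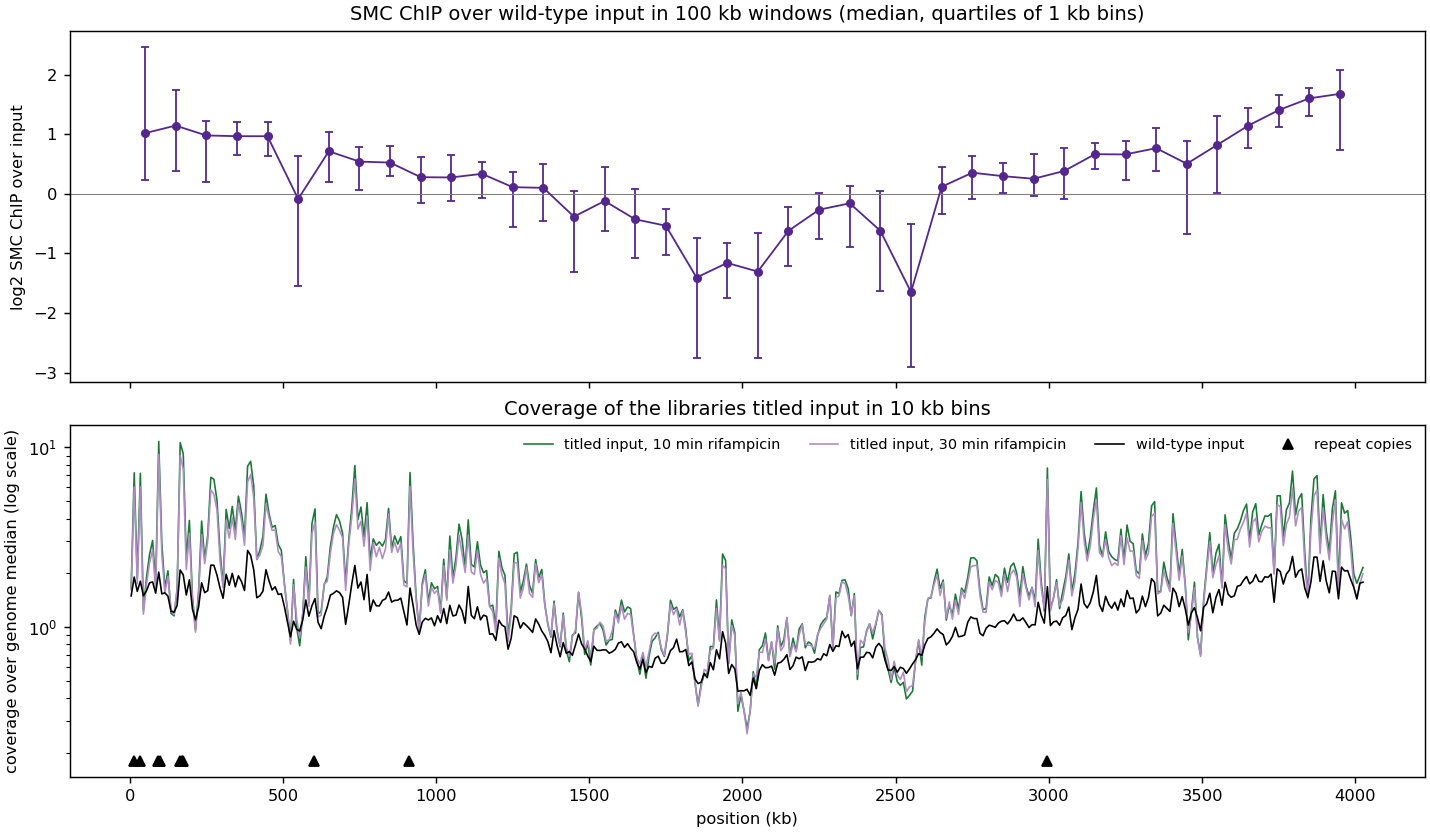
Top: median log2 SMC ChIP over wild-type input in 100 kb windows against position in kb, with the quartiles of 1 kb bins as bars. Bottom: coverage over the genome-wide median in 10 kb bins (log scale) of the wild-type input and the libraries titled input after 10 and 30 min of rifampicin, with black triangles at the repeat copies. The SMC ratio falls from 1.68 at 3900 to 4000 kb to -1.30 at 2000 to 2100 kb. The rifampicin libraries are high at the copies and also in other places. The 10 min library is at 8.36 in the bin centred on 395 kb, which holds no copy, and at 7.25 in that on 915 kb, which holds a copy.

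Insulation at the repeat copies was read in the 10 bins of 10 kb that hold them. Its median was -0.30 at 0 min of xylose, -0.22 at 30 min, -0.18 at 60 min and -0.14 at 90 min, and the 90 min value lay 0.16 (0.071 to 0.24) above that at 0 min. Of 10000 random lists of 10 bins, 0.21% had a lower median at 0 min. The copies lie close together, however, and when the list was moved around the circle as a block, 43 of 404 positions gave a score as low at 0 min and 47 at 90 min. The median over these positions rose from -0.022 to 0.033, less than that of the copies. The gap of the copies to it therefore narrowed, while their rank within the map hardly changed. Under rifampicin the medians were -0.04 at 10 min and -0.14 at 30 min, a difference of -0.095 (-0.16 to -0.041), but 160 and 93 of 404 positions of the list gave a score as low, so the copies stand out in neither map.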

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

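All tests in this part were chosen after the coverage values they use had been seen.

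Outside the repeat copies, the libraries titled input after rifampicin held high bins, which the report compares only as a group. Of 3974 bins of 1 kb, 89 lay above 4 times the local median after 10 min of rifampicin and 63 after 30 min, against 0 in the wild-type input. The highest bin in both was 533001 to 534000, at 12.1 times the local median after 10 min and 9.43 times after 30 min. The wild-type input was at 2.05 times there, and the SMC ChIP at 7.08 times. The wild-type input thus shares this signal at lower amplitude, as the correlations outside the copies (r = 0.838 and 0.808) also show.

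The first pattern weighed is the signal at the repeat copies in the rifampicin libraries titled input. The copies were located with the strongest run of the 30 min library, within limits on its level, so high coverage there follows in part from that choice, and the 10 min library has nearly the same profile (r = 0.979). A coverage bias shared with the wild-type input, such as one from base composition or amplification, can therefore be neither excluded nor supported: the copies lay 1.58 residual SDs of single bins above that input's profile after 30 min and 1.85 after 10 min, under the steepest slope that the other bins allow. Whether the libraries may hold immunoprecipitated DNA, as the anti-GFP label says and against their titles, cannot be told either. Their local spread was 2.84 and 2.64 times that of the wild-type input. Outside the copies, 655 and 629 bins lay above 2 times the local median, against 25 in that input, and the choice of copies does not set these counts. The profile outside the copies nevertheless followed the wild-type input (r = 0.838 and 0.808), so a wider spread alone does not decide. The copies lay 2.39 and 2.23 residual SDs above the ordinary regression on that input, a height that follows in part from their choice. Input of the same strain was not analysed here, and a difference in strain or a response to rifampicin stays open and untested.

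The second pattern is the SMC signal at the same copies. If a bias shared by all 4 libraries were the whole cause, bins outside the copies that match them in the other 3 libraries would carry as much SMC: their lists had a median of 2.11 times the local median against 9.31 at the copies, a log2 difference of 2.14, and 99.99% of 10000 lists of 10 lay lower. Such lists count the copies as 10 independent members, however, and taken singly 94.7% of the 75 matched bins lay lower. Bins directly beside the copies counted as outside them. Among these, SMC stood at 19.3 times the local median at 598001 to 599000 and 13.2 times at 2996001 to 2997000. Elsewhere outside the copies, only 512001 to 513000 (25.8 times) and the run 540001 to 542000 (at most 9.59 times) reached the copies' level. The matched bins at that level are too many for those places alone, so they include a bin directly beside a copy. The percentage of single bins is thus set in part by the surroundings of the repeats. In a regression on those libraries the copies lay 2.06 residual SDs of single bins up, above 99.6% of single blocks. Reads shared between copies may set the evenness of the values, which had been seen before this was proposed. The SMC ratio ranged over only 0.30 between copies, from 3.56 to 3.87. The medians of the 100 kb windows in which their blocks start ranged over 1.23, from -0.09 to 1.14. The lowest of these is the window at 500 to 600 kb, although that copy lies at 601231 to 603730. With the window at 600 to 700 kb instead, at 0.71, the medians ranged from 0.25 to 1.14, a weaker contrast. A shared bias as the whole cause is thus not excluded by the matched bins, how much SMC each copy carries stays open, and no biological explanation of the height was tested.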

How the results depend on the processing

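The straight-line measures, the ChIP not divided by input, and the omission of the repeat copies were chosen after seeing the data. Of 114 alternative values for the comparisons, 79 moved by less than the margin of the reported 95% interval or, for extents and counts of boundaries, stayed within 1.5 times the reported value, and 11 had the opposite sign; the cause of the changes was not tested. The weakening of the hairpin at 30, 60 and 90 min, the loss of contact within 50 kb and the flatter slope at those times, and the lower insulation SD at 60 and 90 min kept their sign under each alternative run.

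For the 30 minus 10 min rifampicin tilt, the difference was -0.14 without smoothing, 0.11 over 200 to 600 kb and 0.23 by straight line. For strength it was 0.083 over 100 to 500 kb and -0.17 along the line. The contact share within 50 kb differed by 0.51 without hairpin pixels, and the decay slope by -0.094 over 30 to 200 kb, which turned its sign. The insulation SD differed by 0.035 with a 50 kb square and by -0.0047 with 200 kb. The 1 shared boundary became 0 within 1 bin and 5 at depth 0.1, where 4 of 404 shifts matched as many. The origin to terminus ratio differed by -0.50 with the terminus at 180 degrees.

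For xylose, extent differed by -3000 kb at 30 and at 60 min with a threshold of 1.5, because the 0 and 90 min maps alone passed it near parS, up to the search limit of 3000 kb on the path through parS. At 90 min the maxima at places away from parS had a median of 1.60, already above this threshold, so passing it there does not show a hairpin. The 50% level was not reached at 60 and 90 min. Tilt differed by 0.099 at 30 min without smoothing. At 90 min it differed by -0.67 without smoothing, -0.069 with 5 x 5 bins, 3.46 with a free start, -0.13 over 200 to 600 kb and -0.40 by straight line. Strength differed by -0.49 at 30 min and -0.39 at 90 min without smoothing, and by -0.82 at 60 min and -0.72 at 90 min over 100 to 500 kb. The slope over 30 to 200 kb differed by 0.045, 0.14 and 0.10 at 30, 60 and 90 min, and the insulation SD by -0.096 at 60 min with a 50 kb square. At depth 0.1, 23, 16 and 18 boundaries were matched at 30, 60 and 90 min. The number of boundaries itself depended on the setting. The 14 at 0 min became 36 with a 50 kb square, 7 with 200 kb and 31 at depth 0.1. The 13 at 90 min became 39, 0 and 43. In the rifampicin maps a 50 kb square gave 3 at 10 min and 9 at 30 min. The insulation difference at the copies was 0.37 with a 200 kb square.

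The SMC difference between origin and terminus was 4.33 without division by input. At the copies the SMC ratio was 2.73 when scaled to total coverage, which shifts every bin by -0.99, and the ChIP alone over its local median gave 3.22.

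Leaving out low rows moved nothing, since balanced maps hold 0 such rows. Leaving out rRNA and tRNA genes was not run for lack of gene positions. No paired analysis was possible because each group has 1 library. The disagreement of the tilt measures at 90 min was not reproduced by simulated noise of 60%, which gave 1.77 and 1.81, and its cause is open.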

Other observations

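Among the tests here, that on random ligations was set out before its value was known, and its observed values were computed again once the scaling of the line had been corrected from the mean to the median contact at a separation. By its first rule, which asked for all 3 times, it decided nothing. The paired differences and the match beyond 1000 kb, on which the reading here rests, were brought in afterwards. The others were chosen after the data had been seen.

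Some SMC peaks were weak or absent in the other libraries. At 4030001 to 4031000, next to the origin, SMC coverage was 4.39 times the local median, while the wild-type input was at 1.04 and the rifampicin libraries at 0.91 and 0.91. At 512001 to 513000 SMC stood at 25.8 times against 1.14 in the wild-type input, but the rifampicin libraries were raised there too, at 4.47 and 4.5 times. Directly beside repeat copies, SMC stood at 5.07 times at 916001 to 917000 and 6.17 times at 2989001 to 2990000, where the other 3 libraries lay at no more than 1.87. Within regions of low ratio, 2001001 to 2008000 and 2523001 to 2526000 held local SMC maxima. In the bins that lay farthest above a regression on the other libraries, 2003001 to 2004000 and 2524001 to 2525000, SMC was 4.42 and 5.06 times the local median, with a ratio to input of -1.0 and -0.36. The highest bin of the first run, 2001001 to 2002000, stood at 6.67 times, with the rifampicin libraries at 2.07 and 2.17.

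Of the 10 deepest boundaries of the 0 min xylose map, 4 lay in regions of very low or very high wild-type SMC ratio. In the 30 kb around the boundary at 2000001 to 2010000 the median SMC ratio was -3.62, around 2520001 to 2530000 it was -2.71 and around 1840001 to 1850000 it was -1.93, while around 160001 to 170000, which holds repeat copies, it was 3.16. Around the other 6 it lay between 0.20 and 1.71. The median over the 10 was 0.50, against 0.33 over all bins, and 76.3% of 10000 random lists of 10 bins had a lower median. A median cannot detect members at both extremes, and a measure of spread chosen from these same values would only restate them, so whether boundaries favour the extremes stays open. Local wild-type input had a median of -0.057 at the 10 against -0.0010 over all bins, with 6.2% of random lists lower and 17 of 403 shifts as low. The SMC data come from another strain than the maps.

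Map similarity, as Pearson's r over pixels of the smoothed enrichment, was 0.983 between 0 and 30 min of xylose, 0.940 between 0 and 60 min and 0.810 between 0 and 90 min. Between the rifampicin maps it was 0.917. Pixels are not independent.

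The third pattern weighed is the fall of the hairpin over the xylose series. Pixel noise falls short as its cause: the 60 min map has 1.13 times the pixel scatter of the 0 min map, and yet its mean enrichment on the line differed by -1.03 (-1.17 to -0.93). A larger share of random ligations in later maps, which would flatten all features alike, was tested by mixing the 0 min map with a uniform map until its contact within 50 kb equalled that of the later map. The mixed map's mean enrichment of 2.67 lay inside the interval of the 30 min map (2.5 to 2.8). In paired differences, with the mixed-in share held fixed, it lay above the observed value by 0.045 (0.017 to 0.075) at 30 min. At 60 min it was 2.13, above by 0.15 (0.092 to 0.23), and at 90 min 2.04, above by 0.20 (0.095 to 0.31). With contact beyond 1000 kb matched instead it lay above by 0.25, 0.47 and 0.26 at 30, 60 and 90 min. Under both matches random ligations may account for a large part of the fall and fell short of the whole. At 90 min, however, the map mixed to contact within 50 kb had a decay slope of -0.45 against -0.30 observed. A match at 50 to 200 kb was not run, so at 90 min random ligations as the whole cause are not excluded. The loss of RNA polymerase that xylose is meant to bring about, xylose itself and time in culture cannot be separated here, as maps of a strain without the tag were not analysed and no RpoC level is part of the data used here.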
